A study of Mus musculus with 8 samples.

How the data were processed

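RNA-seq was performed on 8 subcutaneous tumors grown in mice from MC38-OVA, a mouse colon adenocarcinoma line that carries the model antigen ovalbumin. The genotype label reads shNT for 4 tumors and shXBP1, a hairpin against Xbp1, for the other 4. Total RNA of whole tumors was used, so each library holds RNA of tumor cells and of the host cells among them. Samples were grouped by the genotype in their labels, and a tumor is named here by its group and number.

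The deposited table holds, per the file headers, raw counts and FPKM for each tumor, together with the authors' comparison of the groups. The counts were deposited without normalization, as whole numbers, 1 column per tumor. Whether a count stands for a read or a fragment is not given in the sources used here. Among nonzero counts, 0.817% equalled 1 and 3.21% equalled 2. The FPKM values, counts scaled by the authors to gene length and library size per the file headers, were read but not used in any test. The authors' comparison was made with DESeq2, per the file headers, and gives a log2 fold change and an adjusted p for 13307 genes. The genome build was GRCm38, per the submitters' processing notes. The aligner, the counting tool, the strand setting and the annotation release are not given in the sources used here. The table has 25766 entries, of which 22036 are annotated genes and 3730 are loci that the authors' table lists as new. Of the annotated identifiers, 22022 were found in the GENCODE M21 annotation of GRCm38, from which the coordinates were taken. For the 21 symbols shared by more than 1 identifier, the identifier with the highest total was used.

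Total counts ranged from 29070605 to 36012997 per tumor. Genes with low counts were removed with filterByExpr of edgeR, which left 14907 genes. Libraries were scaled by TMM factors, which lay between 0.980 and 1.04. Groups were compared with the quasi-likelihood test of edgeR (version 4.0.16, in R 4.3.3; robust dispersions, no covariate, all 8 tumors), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Values are given as CPM (counts scaled to a common library size) with the SD over 4 tumors, and log2 fold changes are shXBP1 minus shNT with their standard error (SE). Mean log2 CPM used a prior count of 2. A group with 0 counts was given a floor of 3 counts over the group, and this floor covers counting error only.

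Before the data were examined, 31 gene lists were fixed for pathways and for cell types that such tumors could hold, along with the tests and the alternatives. The 28 lists with at least 5 tested members were tested with camera of limma (version 3.58.1) on voom log2 CPM, two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over these lists. The test was repeated with a correlation estimated from the data, and with fry, which asks whether the members of a list move one way and does not compare them with other genes. GO and KEGG terms with 10 to 300 tested members, as the deposited table pairs them with genes, were tested in the same way. The genes named were set by rule: 14 genes fixed beforehand; in each direction the 10 called genes with the largest log2 fold change among those with at least 1 CPM in the higher group and no overlap between groups, leaving out predicted genes and receptor segments; up to 4 members of each list with the smallest p; and every gene in which 1 tumor lay far from its group. List symbols with no entry in the table (Srpra, Ero1b, Ero1a, Trac, Trbc1, Trbc2, Ighm, Igkc, Nox2 and Ahsp) were left out, as were members below the filter. Of the genes this rule names, 3 are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

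The alternatives were DESeq2 (version 1.42.0) and limma voom in place of edgeR, other size factors, no filter or a filter of 10 CPM in 4 libraries, no robust estimation, the tumor number as a block, 1 surrogate variable (sva, version 3.50.0), other thresholds, and leaving out each tumor in turn. The log2 CPM of Ptprc as a covariate was added after the data had been seen. The procedure was tested on simulated counts for shXBP1 against shNT over 14702 genes with 200 genes drawn to change. It recovered 43.8% of 80 genes changed 1.5-fold, 74.7% of 79 changed 2-fold and 90.0% of 40 changed 4-fold, and 5.11% of its calls were genes simulated as unchanged. In simulated data with no change it called 2 genes and 1 of 28 lists. The simulated genes were drawn independently, so this does not show how often lists whose members vary together are called. The 200 changed genes were also far fewer than the 4475 called in the data. The lowest chi-square per degree of freedom between 2 tumors of a group was 16.5, far above the 1 that repeated sequencing of a library would give.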

Results

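RNA-seq counts of 8 subcutaneous tumors were compared, 4 grown from shNT and 4 from shXBP1 cells of MC38-OVA, a mouse colon adenocarcinoma line that carries ovalbumin. The series asks how XBP1, a transcription factor of the unfolded protein response, acts within cancer cells on cholesterol production and on the myeloid cells of the tumor. Total counts were 32380447, 31377627, 29070605 and 32316375 in shNT tumors 1 to 4, and 31152334, 31703034, 34754132 and 36012997 in shXBP1 tumors 1 to 4. The labels number the tumors and do not say whether each came from its own mouse, so p-values measure the spread between these samples.

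In shXBP1 tumors the genes of cholesterol synthesis fell together, 23 of 25 measured, while genes of T cells, cytotoxic lymphocytes, macrophages and interferon-gamma signalling rose. Cyp51, the lanosterol demethylase of cholesterol synthesis, was 3.48-fold lower (440.4 ± 40.7 CPM in shNT and 126.6 ± 22.9 CPM in shXBP1, SD, n = 4 each). Gzmb, the granzyme that cytotoxic lymphocytes release, was 3.72-fold higher (48.9 ± 12.1 and 182 ± 13.5 CPM, SD, n = 4 each). Xbp1 itself was 1.43-fold lower, and the list of XBP1 and ER protein folding genes showed no net shift. Ptprc, which encodes the pan-leukocyte antigen CD45, was 2.73-fold higher in shXBP1 tumors (log2 fold change 1.45, SE 0.22, adjusted p = 0.00128).

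Xbp1 (ENSMUSG00000020484, GRCm38 chromosome 11, 5520659 to 5525893, plus strand) was lower in each shXBP1 tumor than in any shNT tumor. Its level was 97.3, 96.0, 102.5 and 109.2 CPM in shNT tumors 1 to 4, and 77.2, 76.0, 73.7 and 56.6 CPM in shXBP1 tumors 1 to 4. The log2 fold change was -0.51 (SE 0.10, adjusted p = 0.00255), and the authors' deposited table gives -0.50. Of 59 measured genes for ER protein folding, translocation and degradation, 11 rose, 7 fell and 41 did not pass. Adjusted over the list alone, 12 rose and 7 fell. The median log2 fold change was 0.02, and the list did not differ from other genes (camera, adjusted p = 0.979). The number that rose was 7 without shNT tumor 1, 5 without shNT tumor 2, 6 without shNT tumor 4, 5 without shXBP1 tumor 1 and 5 without shXBP1 tumor 3. With the tumor number as a block 5 rose, and with 1 surrogate variable 13 fell. Serp1, which stabilizes membrane proteins at the translocon, fell by 0.49 on the log2 scale (SE 0.08, adjusted p = 0.00115), and Herpud1, of ER-associated degradation, fell by 0.56 (SE 0.10, adjusted p = 0.00121). Sel1l, also of ER-associated degradation, rose by 0.38 (SE 0.08) and Sdf2l1, an ER chaperone component, rose by 0.53 (SE 0.12). Hspa5, the ER chaperone BiP, was at 806 ± 40.3 CPM in shNT and 851 ± 111 CPM in shXBP1 tumors (adjusted p = 0.588), and Dnajb9, a co-chaperone induced by XBP1, was at 18.9 ± 3.64 and 19.8 ± 2.61 CPM (adjusted p = 0.762, SD, n = 4 each).

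Genes of the PERK-ATF4 branch of the stress response fell. Of 23 measured members 16 fell, 1 rose and 6 did not pass, and adjusted over the list alone 18 fell and 1 rose. The list was lower (camera, adjusted p = 9.20e-08; adjusted p = 0.204 with an estimated correlation), with a median of -0.65. The largest of the 4 members named by rule was Cth, an enzyme of cysteine synthesis, 3.98-fold lower. Vldlr, a lipoprotein receptor, was at 72.4 ± 15.6 and 30.7 ± 5.23 CPM, Psat1, of serine synthesis, 1.71-fold lower, and Nupr1, a stress-induced transcription regulator, 1.56-fold lower. The member that rose was Atf3, by 0.71 (chosen after its value was seen). With the log2 CPM of Ptprc as a covariate edgeR called 0 members, 4 were lower at an unadjusted p under 0.05, and the median was -0.45. Camera still called the list lower (adjusted p = 0.00526, and 0.590 with an estimated correlation).

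At a threshold of 0.05 on the adjusted p of edgeR's quasi-likelihood test, 2517 of 14907 genes were higher and 1958 were lower in shXBP1 tumors, 30.0% of the genes tested. Of these, 1138 were higher and 166 were lower by at least 2-fold. The groups did not overlap for 30.2% of genes, against 2.86% by chance. The authors' deposited table has 834 genes higher and 95 lower at an adjusted p below 0.01 and at least 2-fold, and its sign was the same for all 4258 genes called here that it gives a value. The first principal component held 52.1% of the variance and separated the groups. On it the shNT tumors lay between -52.0 and -28.1, shXBP1 tumors 1 to 3 between 43.1 and 48.7, and shXBP1 tumor 4 at 16.2. Without shXBP1 tumor 4, 2904 genes were higher and 2401 were lower. Without shNT tumor 3, 1303 were lower.

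**Figure D1:**
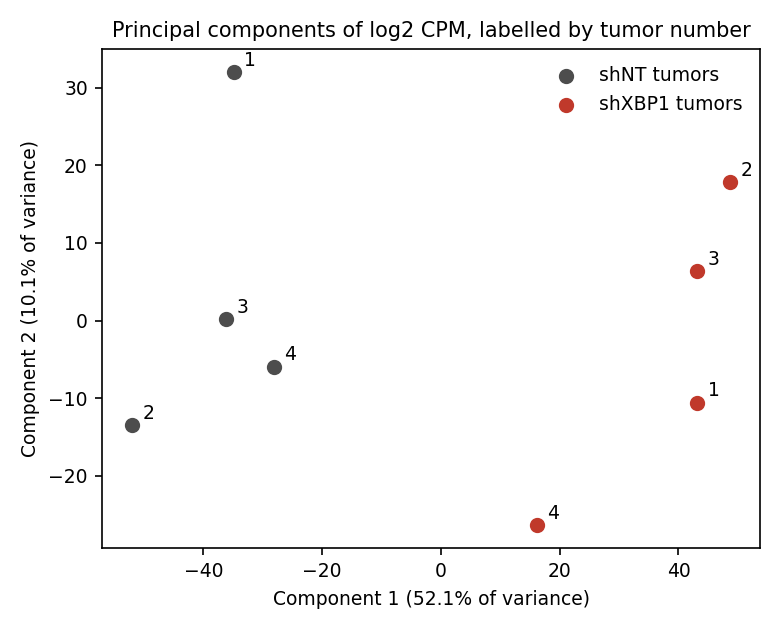
Principal components of log2 CPM over the 14907 tested genes, with component 1 (52.1% of variance) on the x axis, component 2 (10.1%) on the y axis, and 1 point per tumor, numbered as in the labels. The groups lie apart on component 1, with shXBP1 tumor 4 (16.2) nearest to the shNT tumors.

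The list of cholesterol biosynthesis and uptake had the lowest median among the tested lists, -1.53. All 25 members were measured, 23 fell, and Tm7sf2 (log2 fold change -0.04) and Ebp (0.00) did not pass (both chosen after their values were seen). Adjusted over the list alone, 23 fell. The list test gave an adjusted p of 2.16e-20 with camera, and adjusted p = 0.109 with an estimated correlation. Sqle, squalene epoxidase (chromosome 15, 59315077 to 59331192), was 2.85-fold lower (234 ± 23.5 and 82.0 ± 16.9 CPM, adjusted p = 2.35e-05). Fdft1, squalene synthase, was 2.95-fold lower, Msmo1, a sterol monooxygenase, 3.34-fold lower, and Pmvk, phosphomevalonate kinase, 2.32-fold lower. Leukocyte genes moved the other way in the same tumors, and with the log2 CPM of Ptprc as a covariate 7 members fell and the median was -0.87 (camera, adjusted p = 5.78e-13; adjusted p = 0.242 with an estimated correlation). The SE of a gene was then 2.26 times as large at the median.

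Fatty acid synthesis genes fell too, 10 of 16 measured with 6 not passing, and 13 when adjusted over the list alone (camera, adjusted p = 9.28e-09; adjusted p = 0.113 with an estimated correlation). Scd2, a stearoyl-CoA desaturase, was 3.24-fold lower, Elovl6, a fatty acid elongase, 3.03-fold lower, Acly, ATP citrate lyase, 2.02-fold lower and Scd1 1.75-fold lower. With the Ptprc covariate 2 members fell and 8 were lower at an unadjusted p under 0.05. Camera then gave an adjusted p of 0.000985, and 0.260 with an estimated correlation. In contrast, genes of cholesterol efflux, storage and liver X receptor targets rose, 13 of 16, with 1 that fell and 2 that did not pass. The counts adjusted over the list alone were 13 and 1 (camera, adjusted p = 8.59e-07; adjusted p = 0.138 with an estimated correlation). The cholesterol exporters Abcg1 and Abca1 were 4.51-fold and 2.80-fold higher, Plin2, which coats lipid droplets, 2.57-fold higher, and Mylip, a ubiquitin ligase, 2.48-fold higher. Scarb1, a lipoprotein receptor, was the member that fell, by 0.90 (chosen after its value was seen). With the Ptprc covariate 1 member rose, while 5 were higher and 1 was lower at an unadjusted p under 0.05. Camera then gave the efflux list an adjusted p of 0.0296, and 0.392 with an estimated correlation.

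**Figure D2:**
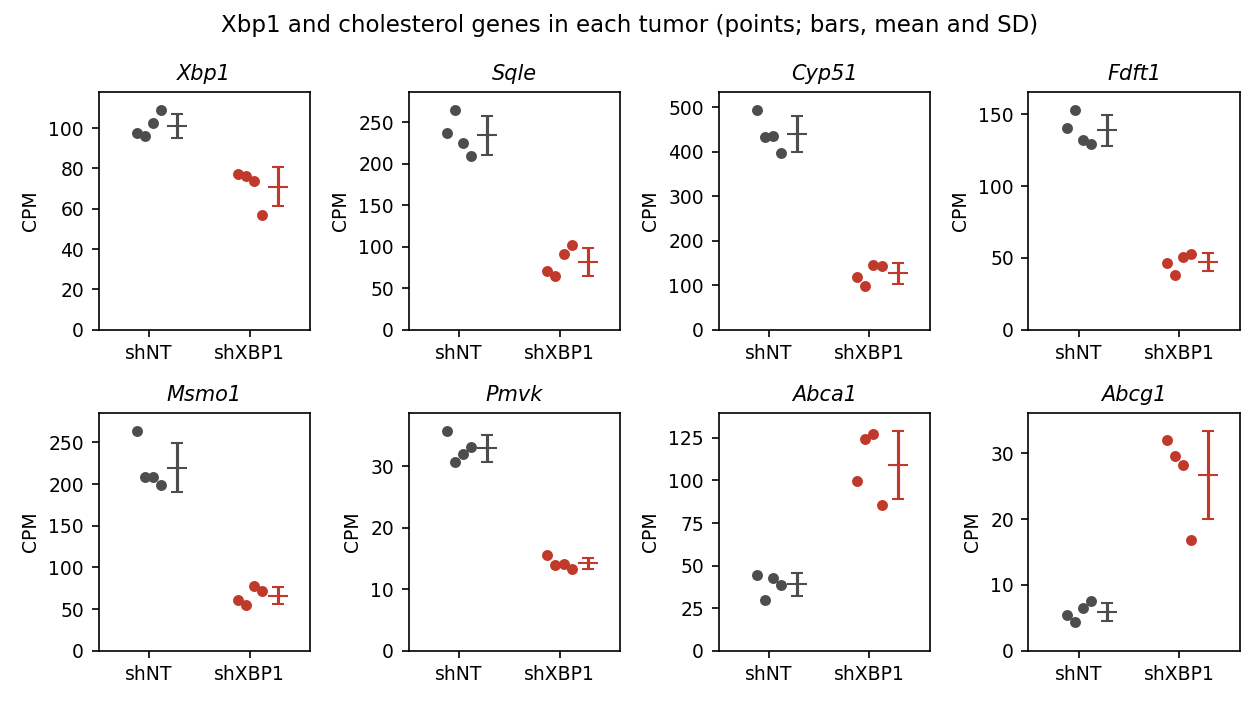
CPM (y axis, from 0) of Xbp1, 5 genes of cholesterol synthesis and 2 cholesterol exporters in the shNT and shXBP1 tumors (x axis), with 1 point per tumor in order of number and bars for the mean and SD (n = 4). Sqle had a mean of 234 CPM in shNT and 82.0 CPM in shXBP1 tumors, and the groups do not overlap for any of the 8 genes.

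Lymphocyte genes rose. All 17 measured T cell genes rose (17 adjusted over the list alone), with a median of 1.98, as did 18 of 19 genes of cytotoxic lymphocytes (18 adjusted over the list alone, 1 not passing), with a median of 1.98. The T cell list gave an adjusted p of 2.96e-09 with camera and adjusted p = 0.204 with an estimated correlation. The cytotoxic list gave 9.98e-12 and adjusted p = 0.1197 with an estimated correlation. Cd3e, of the T cell receptor complex, was at 4.21 ± 1.07 CPM in shNT and 16.4 ± 5.69 CPM in shXBP1 tumors, 3.88-fold higher (adjusted p = 0.00102). Cd8a, the coreceptor of cytotoxic T cells, was 3.95-fold higher (adjusted p = 0.00672; with the tumor number as a block log2 fold change 1.92, adjusted p = 0.0527), and Ifng, the cytokine interferon-gamma, 5.16-fold higher (23.0 ± 9.75 against 4.45 ± 1.30 CPM, adjusted p = 0.00273). Cd28, a T cell costimulatory receptor, was 5.18-fold higher, and Icos, another, 4.27-fold higher. Checkpoint and exhaustion genes rose in all 12 cases (12 adjusted over the list alone; camera, adjusted p = 6.58e-08; adjusted p = 0.109 with an estimated correlation). Cd274, which encodes PD-L1, was 2.96-fold higher (63.9 ± 13.7 and 189 ± 29.3 CPM, adjusted p = 7.40e-05), and Ctla4 was 2.99-fold higher. Of 8 regulatory T cell genes 7 rose and 1 did not pass (7 adjusted over the list alone; camera, adjusted p = 0.000182; adjusted p = 0.109 with an estimated correlation), with Il2ra, an interleukin 2 receptor chain, 2.81-fold higher. Of 12 natural killer cell genes 10 rose, 1 fell and 1 did not pass, and the counts adjusted over the list alone were 10 and 1 (camera, adjusted p = 1.22e-05; adjusted p = 0.138 with an estimated correlation). Ncr1, an activating receptor of these cells, was 2.98-fold higher. Klra4, the member that fell (log2 fold change -0.63, chosen after its value was seen), and Klra7, 5.40-fold higher, have close copies in the same family, among which the counting could split reads. Of the B and plasma cell list only 4 genes were measured. Cd22 and Cd79b rose, 2.12-fold and 3.62-fold, each at under 3 CPM, and Pax5 and Cr2 did not pass. The call of Cd79b was lost without shNT tumor 2 (adjusted p = 0.0770), shNT tumor 4 (0.0617), shXBP1 tumor 1 (0.0592), 2 (0.0763) or 3 (0.0563), and that of Cd22 without shXBP1 tumor 1 (0.0547). With the log2 CPM of Ptprc as a covariate edgeR called 0 of the T cell genes (3 higher and 1 lower at an unadjusted p under 0.05) and 1 of the cytotoxic genes (6 higher unadjusted). It called 0 checkpoint, 0 regulatory T cell and 0 natural killer cell genes (4, 1 and 3 higher unadjusted). Camera still called these lists higher (adjusted p = 0.00673, 0.0231 and 0.0161), but not with an estimated correlation (0.260, 0.268 and 0.268). The cytotoxic list was also still called higher by camera (adjusted p = 0.000545, and 0.268 with an estimated correlation). The T cell list was not (camera, adjusted p = 0.593). Ptprc stood at 59.4, 42.6, 66.5 and 56.4 CPM in the shNT tumors and at 156, 193, 171 and 94.8 CPM in the shXBP1 tumors.

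Myeloid genes rose as well. Of 21 macrophage and monocyte genes 18 rose and 3 did not pass, with 19 that rose adjusted over the list alone (camera, adjusted p = 7.69e-11; adjusted p = 0.195 with an estimated correlation). Cd68, a lysosomal protein of macrophages, was 2.50-fold higher, Fcgr1, an immunoglobulin receptor, 2.84-fold higher, and Cd14, the coreceptor for lipopolysaccharide, 2.17-fold higher. Of 12 genes of neutrophils and granulocytic myeloid cells 7 rose and 5 did not pass, and adjusted over the list alone 8 rose (camera, adjusted p = 0.000123; adjusted p = 0.109 with an estimated correlation). S100a8, an abundant protein of neutrophils, was at 0.935 ± 0.215 CPM in shNT and 3.95 ± 0.796 CPM in shXBP1 tumors (adjusted p = 0.00015), and Csf3r, the receptor for granulocyte colony-stimulating factor, was 3.97-fold higher. Ly6g, a neutrophil surface marker, was below the filter, with 11 counts in all in the shXBP1 tumors and 0 in the shNT tumors, and was not tested. Under the Ptprc covariate edgeR called 0 macrophage genes (3 higher and 3 lower at an unadjusted p under 0.05) and 3 neutrophil genes as higher. Of the 12 neutrophil genes 8 were then higher at an unadjusted p under 0.05, with a median of 1.96 (camera, adjusted p = 1.01e-08, and 0.0690 with an estimated correlation). The log2 ratio of the list to Ptprc, chosen after results were seen, differed by -0.18 (two-sided exact permutation p = 0.714). In its group shXBP1 tumor 4 had the lowest Ptprc (94.8 CPM) and the highest mean log2 CPM of this list (3.05, others 2.351 to 2.64). The neutrophil fit without that tumor is not given here.

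The list of myeloid immunosuppression rose in 16 of 21 measured genes, with 1 that fell and 4 that did not pass, and the counts adjusted over the list alone were 16 and 1. Its call held with an estimated correlation, which was low for this list at 0.0195 (camera, adjusted p = 2.86e-08, and 0.0269 with the estimate). The log2 ratio of the list to Ptprc, chosen after results were seen, differed by -0.32 (two-sided exact permutation p = 0.229). Arg1, the arginase of myeloid cells (chromosome 10, 24915221 to 24927484), was 1.61-fold higher (346 ± 58.5 and 556 ± 85.2 CPM, log2 fold change 0.68, SE 0.14, adjusted p = 0.0032). Nos2, inducible nitric oxide synthase, was 6.19-fold higher (29.6 ± 6.57 and 183 ± 34.3 CPM, adjusted p = 1.38e-05). Ptgs2, a prostaglandin synthase, was 3.19-fold higher and Il1b, the cytokine interleukin 1 beta, 3.10-fold higher, and both also belong to inflammatory responses. Vegfa, an endothelial growth factor, was the member that fell, by 0.34 (chosen after its value was seen). That call was lost when shNT tumor 1, 2 or 3 or shXBP1 tumor 1, 2 or 3 was left out, with the tumor number as a block, and under a filter of 10 CPM in 4 libraries. Given the Ptprc covariate, 2 members of this list rose and 9 were higher at an unadjusted p under 0.05, and 0 fell (0 lower unadjusted). The list of myeloid-recruiting chemokines and growth factors rose in 12 of 15 genes, with 1 that fell and 2 that did not pass, and adjusted over the list alone 12 rose and 2 fell. Il34, a growth factor for macrophages, was the member that fell, by 0.38 (chosen after its value was seen), and that call was lost without shNT tumor 2 or 3 or shXBP1 tumor 1, 2 or 3, while 2 members fell without shXBP1 tumor 4. The call of the chemokine list also held (camera, adjusted p = 1.92e-06, and 0.0269 with an estimated correlation, which was -0.0456). Ccl3 was 5.14-fold higher, Cxcl12 4.28-fold, Ccl7 3.48-fold and Cxcl1 3.18-fold. Of the chemokine list 5 genes still rose given that covariate, and 10 were higher at an unadjusted p under 0.05. The mean log2 CPM of the chemokine list was highest of its group in shXBP1 tumor 4 (5.29, others 5.17 to 5.23). Ptprc was lowest of its group in that tumor. Of 13 dendritic cell genes 9 rose, 1 fell and 3 did not pass, and adjusted over the list alone 10 rose and 1 fell (camera, adjusted p = 0.000704; adjusted p = 0.150 with an estimated correlation). Ccr7, the homing receptor of migrating dendritic cells, was 5.36-fold higher and Ccl22, a chemokine they secrete, 2.59-fold higher. Fscn1, an actin-bundling protein, was the member that fell, by 0.44 (chosen after its value was seen), and that call was lost when shNT tumor 2, 3 or 4 or shXBP1 tumor 1, 2 or 3 was left out, with the block, and without a filter or under that filter. The number of dendritic cell genes that rose was 4 without shNT tumor 2, 5 without shNT tumor 3 and 5 without shXBP1 tumor 3. Given the Ptprc covariate edgeR called 0 of them, with 0 higher and 1 lower at an unadjusted p under 0.05 (camera, adjusted p = 0.328).

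**Figure D3:**
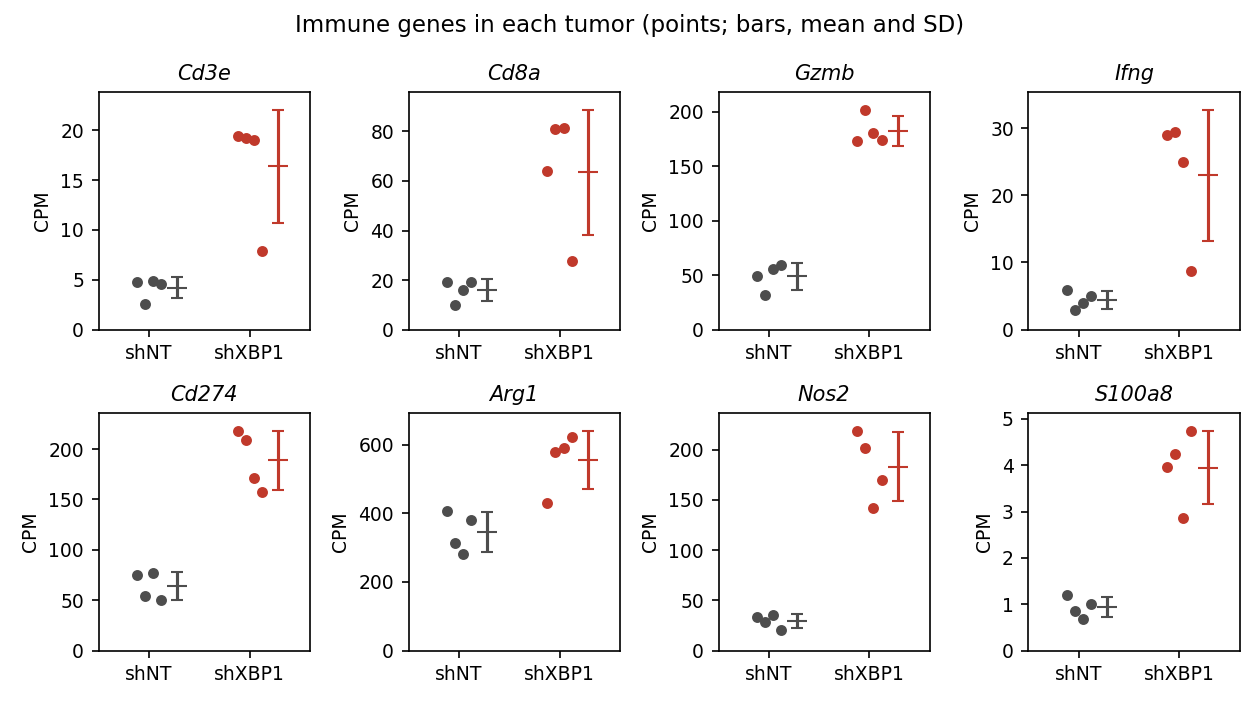
CPM (y axis, from 0) of 8 immune genes in the shNT and shXBP1 tumors (x axis), with 1 point per tumor in order of number and bars for the mean and SD (n = 4). Each gene was higher in the shXBP1 tumors, from 1.61-fold for Arg1 to 6.19-fold for Nos2, and Cd3e was at 7.85 CPM in shXBP1 tumor 4.

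All 29 genes of antigen presentation and the interferon-gamma response rose (29 adjusted over the list alone; camera, adjusted p = 3.14e-16; adjusted p = 0.177 with an estimated correlation), with a median of 1.10. Tap1 and Tap2, the peptide transporter for MHC class I, were 1.92-fold and 1.90-fold higher, and Irf1, a transcription factor induced by interferon, 1.81-fold higher. H2-Q7, a class I gene with close copies among which reads could be split, was 3.43-fold higher. Of 20 type I interferon response genes 11 rose and 9 did not pass, and adjusted over the list alone 14 rose (camera, adjusted p = 5.58e-07; adjusted p = 0.267 with an estimated correlation). Without shXBP1 tumor 4, 18 rose. Oas2 and Oas3, sensors of double-stranded RNA, were 2.91-fold and 1.78-fold higher, and Zbp1, a nucleic acid sensor, 2.37-fold higher. Given Ptprc as a covariate, edgeR called 0 genes of either list, with 3 higher and 1 lower of the first list and 0 of the type I list at an unadjusted p under 0.05.

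Genes of stromal cells moved in the same direction as those of leukocytes. Of 15 endothelial genes 9 rose and 6 did not pass, and adjusted over the list alone 11 rose (camera, adjusted p = 3.31e-05; adjusted p = 0.109 with an estimated correlation). Pecam1, the endothelial and leukocyte adhesion molecule CD31, was 2.56-fold higher and Cdh5, endothelial cadherin, 1.59-fold higher. Of 17 genes of fibroblasts and extracellular matrix 9 rose, 1 fell and 7 did not pass, and adjusted over the list alone 10 rose and 2 fell (camera, adjusted p = 0.000282; adjusted p = 0.204 with an estimated correlation). Col3a1, a fibrillar collagen, was 3.27-fold higher (1580 ± 413 and 5165 ± 704 CPM), Dcn, decorin, 3.41-fold higher, and Dpt, dermatopontin, 11.1-fold higher. Postn, periostin, was the member that fell, by 0.77 (chosen after its value was seen), and that call was lost without shNT tumor 3 or 4 or shXBP1 tumor 1 or 2, with the block or without a filter, while 2 members fell without shXBP1 tumor 4. Given the Ptprc covariate, 1 endothelial and 2 fibroblast genes rose, and 6 and 8 were higher at an unadjusted p under 0.05. The mean log2 CPM of the fibroblast list was highest of its group in shXBP1 tumor 4 (6.26, others 6.04 to 6.17). Ptprc was lowest of its group in that tumor. Of 7 adipocyte genes 5 rose and 2 did not pass, and adjusted over the list alone 5 rose and 1 fell (camera, adjusted p = 0.00836; adjusted p = 0.138 with an estimated correlation). Without shNT tumor 1, 3 rose. Given the Ptprc covariate edgeR called 0 adipocyte genes and 0 had an unadjusted p under 0.05. Their median was then 0.97 (camera, adjusted p = 0.0296, and 0.268 with an estimated correlation). Pparg, a regulator of fat cell differentiation that macrophages also express, was 5.15-fold higher and Fabp4, a fatty acid carrier, 1.91-fold higher.

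The lists of skeletal muscle, keratinocytes and erythroid cells were not called by camera without a covariate. Of 17 skeletal muscle genes Mb, myoglobin, rose (0.760 ± 0.441 and 3.07 ± 1.16 CPM, adjusted p = 0.00352) and 16 did not pass (list, adjusted p = 0.0857; 1 adjusted over the list alone). The number that rose was 3 without shNT tumor 1 and 2 without shXBP1 tumor 2. Under the Ptprc covariate camera called this list higher (adjusted p = 4.68e-09, and 0.260 with an estimated correlation), with 0 genes called by edgeR and 6 higher at an unadjusted p under 0.05. In its group shXBP1 tumor 4 had the highest mean log2 CPM of this list (2.87, others 1.19 to 1.95) and the lowest Ptprc (94.8 CPM). Of 5 keratinocyte genes 1 fell, 1 rose and 3 did not pass, with the same counts adjusted over the list alone (list, adjusted p = 0.484). Its median was 0.09 and its mean 0.16, while camera pointed down, and fry called the list lower (adjusted p = 0.0245). Members below the filter had counts mostly in shXBP1 tumors. Krt15, a basal keratin, had 0 counts in shNT and 97, 88, 0 and 34 in shXBP1 tumors 1 to 4, Krt5 had 3 and 141 in all, and Trp63, a transcription factor of basal cells, 16 and 74 (chosen after their values were seen). Krt14, a basal keratin, was 3.55-fold lower (175 ± 26.7 and 49.4 ± 2.33 CPM, adjusted p = 2.04e-06), while Dmkn, dermokine, at under 1 CPM, was 3.04-fold higher, a call lost without shNT tumor 2 (adjusted p = 0.0804), shNT tumor 3 (0.0797) or shXBP1 tumor 2 (0.109). The epithelial list had 4 measured genes, among which Lgals4, a galectin, rose 1.52-fold, a call lost without shNT tumor 2 (adjusted p = 0.0557), 3 (0.0825) or 4 (0.0686) or shXBP1 tumor 1 (0.108) or 2 (0.0688). Limma voom did not call it either (0.0505), and adjusted over the list alone 2 rose and 1 fell. Of 2 measured melanocyte genes Mitf rose 1.99-fold. Of 5 erythroid genes 0 passed with edgeR, 0 had an unadjusted p under 0.05, and DESeq2 and limma voom called 0 each (list, adjusted p = 0.199). Hba-a1 was at 16.5 ± 11.7 CPM in shNT and 9.71 ± 8.81 CPM in shXBP1 tumors, and its reads can be split with Hba-a2.

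Proliferation and glycolysis genes fell by small amounts. Of 24 cell cycle genes 11 fell and 13 did not pass (11 adjusted over the list alone; camera, adjusted p = 6.41e-06; adjusted p = 0.267 with an estimated correlation), with a median of -0.24. Kif11, a motor of the mitotic spindle, fell by 0.58 on the log2 scale and Mcm6, of the replicative helicase, 1.36-fold lower. The number that fell was 7 without shNT tumor 1, 2 or 3, and likewise 7 without shXBP1 tumor 1, 2 or 3. It was 6 with the tumor number as a block and 7 under a filter of 10 CPM in 4 libraries. Of 20 hypoxia and glycolysis genes 10 fell, 1 rose and 9 did not pass, with the same counts adjusted over the list alone. Camera called the list lower (adjusted p = 0.0178, and 0.487 with an estimated correlation), but fry did not call it (adjusted p = 0.0769). Ldha, lactate dehydrogenase, was 1.52-fold lower and Pgk1, phosphoglycerate kinase, 1.53-fold lower. Pfkfb3, which promotes glycolysis, was the member that rose, 2.51-fold. The number that fell was 6 without shNT tumor 1 or 3. Under the Ptprc covariate edgeR called 0 cell cycle genes (1 higher and 2 lower at an unadjusted p under 0.05) and 0 hypoxia and glycolysis genes (2 higher and 5 lower). Immediate early genes rose in 9 of 13 cases, with 4 not passing and 12 adjusted over the list alone (camera, adjusted p = 1.64e-06; adjusted p = 0.109 with an estimated correlation), such as Btg2, 3.29-fold higher, and Zfp36, 2.87-fold higher. Of these 13 genes 7 rose under that covariate and 11 were higher at an unadjusted p under 0.05. Their median was then 1.02, against 0.52 without it. Their mean log2 CPM was highest of its group in shXBP1 tumor 4 (6.02, others 5.76 to 5.79). Ptprc was lowest of its group in that tumor (94.8 CPM). Among 21 genes of extracellular vesicle release 5 rose, 2 fell and 14 did not pass, and adjusted over the list alone 5 rose and 3 fell (list, adjusted p = 0.871). Smpd3, a sphingomyelinase, fell by 1.05 (chosen after its value was seen), and the tetraspanin Cd63 and the adaptor Sdcbp rose. The GTPases Rab27a and Rab27b moved apart, Rab27a 2.39-fold higher and Rab27b 1.95-fold lower. Of 13 mitochondrially encoded genes 0 passed with edgeR, 0 had an unadjusted p under 0.05, and DESeq2 and limma voom called 0 each (list, adjusted p = 0.875). Without shXBP1 tumor 4, 1 of them rose. Under the Ptprc covariate 3 fell and 11 were lower at an unadjusted p under 0.05, with a median of -0.90. Camera then gave an adjusted p of 2.43e-10, and 0.260 with an estimated correlation. The mean log2 CPM of the mitochondrial list was lowest of its group in shXBP1 tumor 4 (9.73, others 9.92 to 10.5), as was Ptprc.

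**Figure D4:**
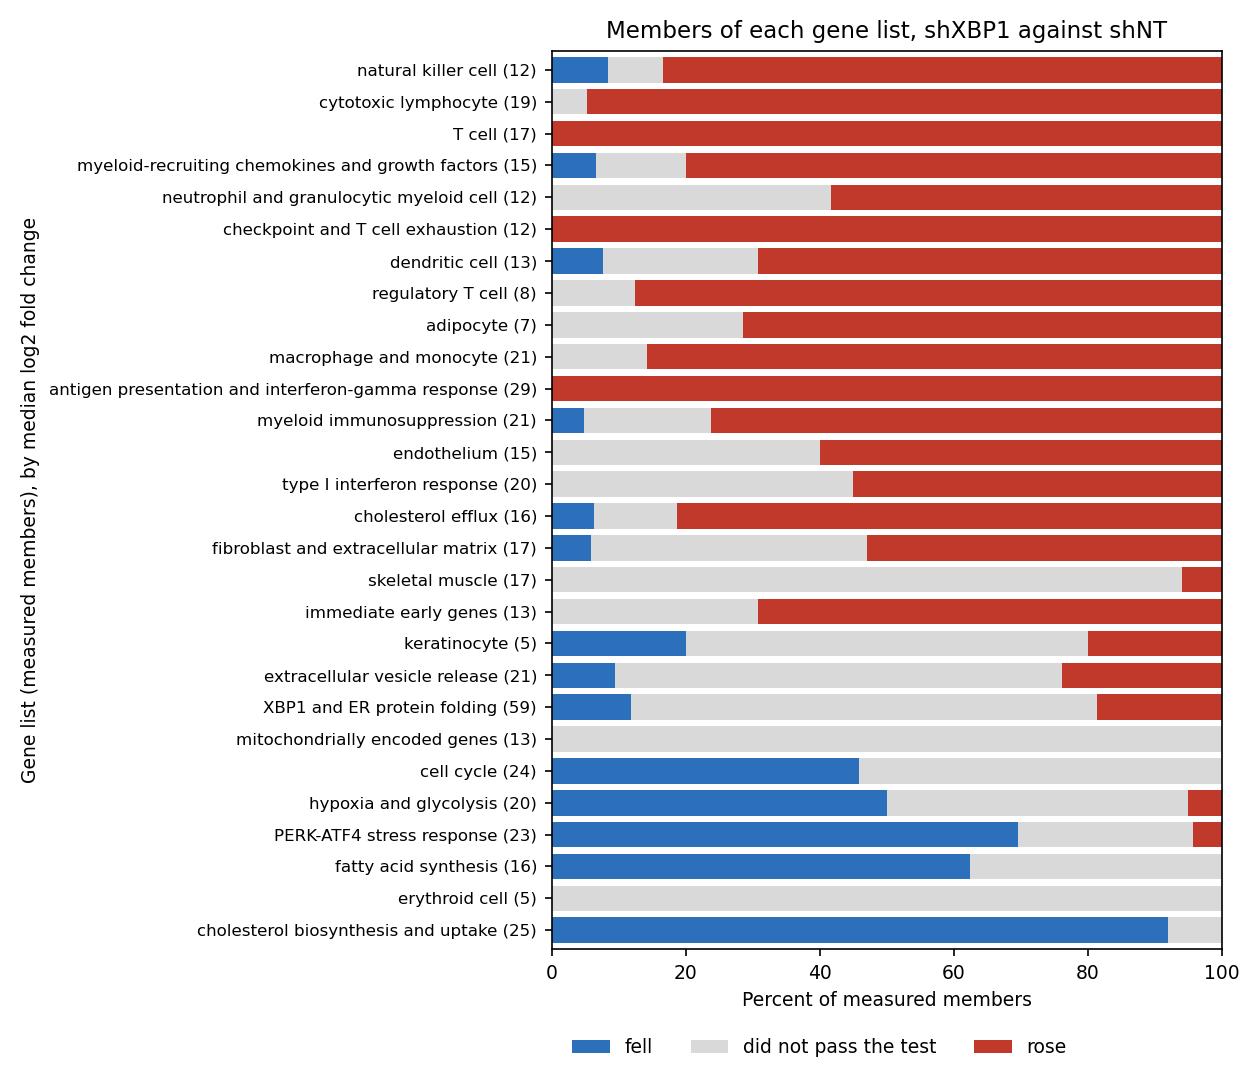
Percent of the measured members of each of the 28 tested gene lists (x axis) that fell, did not pass the test or rose in shXBP1 tumors, with lists on the y axis ordered by median log2 fold change and measured members in brackets. Of the cholesterol biosynthesis and uptake list 23 of 25 members fell, and of the T cell list 17 of 17 rose.

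The single genes with the largest rise by rule were Akr1c14, an aldo-keto reductase (0.392 CPM in shNT and 6.44 CPM in shXBP1 tumors, 16.2-fold, SE 0.33 on the log2 scale, adjusted p = 1.23e-05), and the mast cell proteases Cpa3 (15.4-fold), Cma1 (14.0-fold) and Mcpt2 (10.8-fold), with Fcer1a, a chain of the IgE receptor, at 0.172 ± 0.199 CPM in shNT and 1.97 ± 0.592 CPM in shXBP1 tumors. Ogn, an extracellular matrix proteoglycan, was 11.4-fold higher, Saa3, an acute-phase protein, 10.5-fold, and Xlr4c, an X-linked gene with close copies, 10.8-fold. Limma voom did not call Xlr4c (adjusted p = 0.0592). Among the 10 genes with the largest fall by rule, Tnnt2, cardiac troponin T (chromosome 1, 135836354 to 135852260), was the most abundant, at 270 ± 34.9 CPM in shNT and 21.5 ± 6.84 CPM in shXBP1 tumors (12.5-fold lower, SE 0.22 on the log2 scale, adjusted p = 1.07e-05). Tmprss11b, a serine protease, had 158 counts in shNT and 0 in shXBP1 tumors, 56.2-fold lower against a floor of 3 counts per group. That floor covers counting error only, and the shNT tumors ranged from 0.561 to 2.52 CPM. Adamts8, a metalloprotease, was 6.58-fold lower, Epha8, an ephrin receptor, 4.90-fold, Lgr6, an R-spondin receptor, 6.78-fold, and P2rx3, an ATP-gated channel, 5.49-fold. Ube2ql1 was 5.34-fold lower, Fam110c 5.31-fold, Dach2 10.0-fold and Car6, a secreted carbonic anhydrase, 5.27-fold. The calls of Dach2 and Car6 were lost without shXBP1 tumor 3 (adjusted p = 0.0519 and 0.0590), and limma voom did not call Car6 (adjusted p = 0.0524). With the tumor number as a block edgeR did not call Lgr6 (adjusted p = 0.0505), Dach2 (0.0524) or Car6 (0.112).

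Among annotation terms, 277 of 2270 GO terms (197 higher, 80 lower) and 109 of 279 KEGG pathways (74 higher, 35 lower) passed camera with the preset correlation. With an estimated correlation camera called 0 of each. Their lowest adjusted p was then 0.533 and 0.164, with 207 and 69 terms at an unadjusted p under 0.05, and fry called 1194 and 201. Outside the fixed lists, 68 of 119 measured genes of the KEGG lysosome pathway rose and 1 fell, with a median of 0.35, and 29 of 51 complement and coagulation genes rose. Of 164 genes of the ribosome pathway 58 fell and 2 rose, with a median of -0.27.

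Camera called 22 of the 28 lists, 17 higher and 5 lower, while 2 were called with an estimated correlation, and up to 25 lists were called under other splits of the tumors. The other splits that called 22 or more had all but 1 tumor of a group on a side, so they kept part of the real contrast. With the log2 CPM of Ptprc as a covariate, added after the data had been seen, 134 genes were higher and 106 were lower. The log2 fold change of Xbp1 was then -1.03 (SE 0.19, adjusted p = 0.0196), but -0.62 (SE 0.33, adjusted p = 0.790) without shXBP1 tumor 4.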

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

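In 23 of 353 groups of 4 values, 1 tumor lay far from the other 3 by Dixon's ratio, and chance gives about 1 in 20. The tests of the 3 patterns weighed here, and what the splits of the tumors would have to show, were worded only after results were seen. Of the 23, 7 were in shXBP1 tumor 4, 4 each in shNT tumors 1 and 4, 2 each in shNT tumors 2 and 3 and shXBP1 tumor 1, and 1 each in shXBP1 tumors 2 and 3.

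In shXBP1 tumor 4 the mean log2 CPM of the cytotoxic lymphocyte list was 4.47, against 5.14 to 5.19 in the others of its group, and that of immediate early genes was 6.02, against 5.76 to 5.79. Its Cd3e was 7.85 CPM (others 19.03 to 19.4) and its Ctsw 10.9 CPM (others 23.5 to 26.0). Its Psat1 was 271 CPM (others 226 to 228), its Rab27b 8.52 CPM (others 6.08 to 6.47) and its Krt14 52.8 CPM (others 48.0 to 48.6). In shXBP1 tumor 1, Ctla4 was 7.65 CPM (others 10.9 to 11.3) and Hba-a1 was 22.8 CPM (others 4.12 to 7.04). In shXBP1 tumor 2, Lgals7 was 3.60 CPM (others 0.578 to 0.988), and in shXBP1 tumor 3, Nupr1 was 84.95 CPM (others 109 to 114).

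In shNT tumor 1, Serp1 was 317 CPM (others 283 to 285), Msmo1 264 CPM (others 199 to 208), Klrb1c 2.84 CPM (others 1.56 to 1.73) and Ttn 3.40 CPM (others 1.90 to 1.98). In shNT tumor 2, Cd3e was 2.62 CPM (others 4.55 to 4.89) and Rab27a 4.04 CPM (others 5.96 to 6.14). In shNT tumor 3, Cr2 was 1.11 CPM (others 0.189 to 0.343) and Il1r2 was 1.73 CPM (others 2.46 to 2.59). In shNT tumor 4, the immediate early genes had a mean log2 CPM of 5.21 (others 4.99 to 5.02), Zfp36 was 29.5 CPM (others 21.4 to 21.7), Btg2 11.2 CPM (others 7.10 to 7.47) and Akr1c14 0.592 CPM (others 0.312 to 0.347).

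The fall of cholesterol synthesis genes came with a rise of leukocyte genes, so fewer tumor cells per library could lower them. A lower share of tumor cells would also lower other genes made mainly by tumor cells, which were not picked out here. Of the 4819 other genes at 50 CPM or more, 0.145% fell as far as the median of the list. With the log2 CPM of Ptprc as a covariate the mean log2 CPM of the list differed by -0.74 (95% interval -1.38 to -0.09), against -1.40 (-1.78 to -1.02) without it, and the fitted members that fell went from 23 to 7 as the SE grew 2.26-fold at the median. The list thus fell further than nearly all other abundant genes, and a part of its fall remained with the covariate. These values do not decide how much of the fall comes from dilution. The abundant genes include those that host cells may express, and TMM scaling holds the bulk of genes near no change (median log2 fold change -0.005). The covariate stands for leukocytes only, while fibroblast and endothelial genes rose too, and camera with an estimated correlation gave an adjusted p of 0.242. The labels name 1 hairpin against Xbp1, so differences between the injected lines for reasons other than Xbp1 cannot be told apart from an effect of Xbp1 in the tumor cells.

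Xbp1 was 1.43-fold lower in whole tumors, and Xbp1 RNA from host cells, which carry no hairpin, could hide part of the fall in tumor cells. With the log2 CPM of Ptprc as a covariate the log2 fold change of Xbp1 was -1.03 (SE 0.19, adjusted p = 0.0196), and the ER folding list was lower with a median of -0.15 (camera, adjusted p = 0.00166; adjusted p = 0.260 with an estimated correlation). Without shXBP1 tumor 4 the values for Xbp1 were -0.62 (SE 0.33, adjusted p = 0.790) with the covariate and -0.41 (SE 0.08, adjusted p = 0.00114) without it, and the list had a median of -0.16 and an adjusted p of 0.0825. The calls under the covariate were lost without shXBP1 tumor 4, while the list median was not smaller, and masking by host RNA cannot be told apart from a weak knockdown.

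On the first principal component shXBP1 tumor 4 lay between the groups, which RNA of an shNT tumor mixed in, or a wrong label, could give. Such a mix would move risen and fallen genes alike, but on a scale from the other shXBP1 tumors (0) to shNT (1) the median position was 0.583 for 634 risen and 0.214 for 98 fallen genes (difference 0.37, 95% interval 0.315 to 0.417 over 2000 resamples of genes, which are not independent). Its Xbp1 lay at -0.742, away from the shNT tumors, which argues against a wrong label. Fewer infiltrating immune cells in this tumor may account for part of its place, since 46 immune markers lay at 0.702 and 6 stromal markers at 0.215, a difference of 0.487 (95% interval 0.314 to 0.725). This does not extend to granulocytic genes as a whole, since the neutrophil list had the highest mean log2 CPM of its group there (3.05, others 2.351 to 2.64) and S100a8 was 4.74 CPM, while Csf3r was the lowest of its group (12.7 CPM).

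The 8 tumors can be split 4 against 4 in 35 ways, the real one included. A pattern that only the real split reaches has the smallest share the design allows, and the shares were not adjusted over the patterns. Only the real split reached the number of genes higher (2517, reached by 1 split, highest other 2) and lower (1958, 1 split, highest other 2). That only 1 of 35 splits reached these numbers argues against chance. The size of the gap adds nothing to this, since every other split mixes the groups and so widens the spread within a side. The real split was also the highest for GO terms (277, 1 split, highest other 212) and, narrowly, for KEGG pathways (109, 1 split, highest other 104, then 103 and 101). With an estimated correlation camera called 0 of either (207 and 69 at an unadjusted p under 0.05; fry 1194 and 201), and the splits were not counted that way. For the number of lists called chance cannot be excluded, since 6 splits, the real one included, gave 22 or more and the highest other gave 25. Each of the others among the 6 had all but 1 tumor of a group on a side, so it kept part of the real contrast. Only the real split reached the p of the cholesterol list (-log10 p 21.1, 1 split, highest other 11.2) and of the cytotoxic list (11.97, 1 split, highest other 8.21). Neither list was called with an estimated correlation (camera, adjusted p = 0.109 and 0.1197), and their splits were not counted that way. Chance cannot be excluded for the neutrophil list (4.13, 4 splits, highest other 5.98) or the ER folding list (0.00914, 34 splits, highest other 4.52). Each other split that reached the neutrophil value had all but 1 tumor of a group on a side. So did the splits with 104, 103 and 101 KEGG pathways. These splits too kept part of the real contrast.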

How the results depend on the processing

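The Ptprc covariate was chosen after seeing the data, and the other settings were chosen before the data were examined. Xbp1 stayed lower under each of those other settings (log2 fold change -0.56 to -0.41, adjusted p 4.43e-05 to 0.0140). Of the 126 named genes besides Xbp1 that were called, 0 reversed under those settings. Direction and threshold held for 116 of them under each such setting that tested the gene. However, 39 of the 126 lay below the filter of 10 CPM in 4 libraries and were not tested under it. Most of the 126 were named for a small p or a large fold in these data, so these counts do not describe called genes at large. Without 1 tumor, genes higher ranged from 2058 (without shXBP1 3) to 2904 (without shXBP1 4) and genes lower from 1303 (without shNT 3) to 2401 (without shXBP1 4). Adjusted p ranged over 0.567 to 0.978 for the ER folding list, 0.689 to 0.945 for extracellular vesicle release, 0.306 to 0.786 for keratinocytes and 0.144 to 0.945 for mitochondrial genes, with changes of sign. Log2 fold changes ranged from -0.044 to 0.17 for Dnajb9, -0.11 to 0.96 for Cr2, -0.051 to 0.36 for Pmel and -0.31 to 0.021 for mt-Nd4l, none of them called. Genes at 0.01 numbered 1644 higher and 879 lower, and at least 2-fold 1138 and 166, since these thresholds are stricter.

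The labels number the tumors 1 to 4 in each group but state no pairing. Deviations of tumors with the same number correlated at -0.141 to -0.0247, and 0 of 8 tumors correlated best with their own number. With the number as a replicate block 1304 genes were lower and the ER folding list pointed down (adjusted p = 0.992), as it did with 1 surrogate variable (0.756); the cause was not tested. Under the block Cd8a (0.0527), Dach2 (0.0524), Lgr6 (0.0505), Car6 (0.112), Dmkn (0.0698) and Lgals4 (0.0574) lost their calls. Without a filter the keratinocyte list pointed up (0.421). With an estimated correlation camera no longer called the cholesterol (0.109), cytotoxic (0.1197) and neutrophil (0.109) lists. It then called 0 GO and 0 KEGG terms (207 and 69 at an unadjusted p under 0.05, while fry called 1194 and 201). That test allows for members that vary together, but this need not be the whole cause of the losses. For the chemokine list, with an estimate of -0.0456, the adjusted p of camera also rose, from 1.92e-06 to 0.0269.

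With the Ptprc covariate the ER folding list pointed down (camera, adjusted p = 0.00166, but 0.260 with an estimated correlation and 0.0825 without shXBP1 tumor 4). Under this covariate 134 genes were higher and 106 lower, and the macrophage list pointed down (0.522). The log2 fold change turned to -0.29 for Hspa5, -0.50 for Dnajb9, -0.087 for Cd3e, -0.30 for Cd8a, -0.051 for Ifng, -0.51 for Xlr4c, -0.11 for Sdcbp, -0.39 for Cd79b, -1.09 for Cr2, -1.54 for Lgals7, 0.053 for Mcm5, -0.53 for mt-Cytb and -0.65 for mt-Nd4, none called. Ptprc follows the groups, so this covariate also removes what the groups share with it. At this depth members such as Ly6g (0 and 11 counts) were not testable.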

Other observations

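The mast cell list, the ratios to Ptprc and the tests of chromosome 12 were chosen after results were seen. Of 14 measured mast cell genes 11 rose and 3 (Mcpt1, Gata2 and Slc45a3) did not pass. Tpsb2, a tryptase, was 10.5-fold higher (1.52 ± 0.832 and 16.1 ± 5.41 CPM, SD, n = 4 each) and Mcpt4, a chymase, 10.1-fold higher (0.971 ± 0.370 and 9.91 ± 3.35 CPM). Kit, the stem cell factor receptor, was 2.95-fold higher, Hdc, histidine decarboxylase, 2.88-fold, and Il1rl1, the interleukin 33 receptor, 2.64-fold (231 ± 46.1 and 610.3 ± 108 CPM). In shNT tumors Il1rl1 stood far above Tpsb2 (1.52 CPM) and Mcpt4 (0.971 CPM), so its RNA need not come from mast cells. Cpa3, Cma1, Mcpt2 and Fcer1a were among the genes named for the size of their rise.

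Terms of translation and replication were lower by small amounts. Of 44 aminoacyl-tRNA biosynthesis genes 17 fell and 1 rose (median -0.19; camera, adjusted p = 1.97e-05; adjusted p = 0.221 with an estimated correlation). Of 36 DNA replication genes 17 fell and 0 rose (median -0.26; camera, adjusted p = 1.69e-06; adjusted p = 0.205 with an estimated correlation). Of 142 phagosome genes 72 rose and 12 fell (median 0.44; camera, adjusted p = 4.23e-09; adjusted p = 0.164 with an estimated correlation).

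Arg1 rose less than Ptprc, so Arg1 RNA per leukocyte may have been lower in shXBP1 tumors. The log2 ratio of Arg1 to Ptprc was 2.62 ± 0.37 in shNT and 1.89 ± 0.57 in shXBP1 tumors (SD, n = 4 each), a difference of -0.74 (two-sided exact permutation p = 0.0571, adjusted p = 0.121 over 17 ratios). The ratio for Nos2 rose by 1.22 and that for the cytotoxic list by 0.54, while that for the macrophage list differed by -0.27 (each with an exact permutation p of 0.0286, the smallest possible, adjusted p = 0.121). None of the 17 passed after adjustment, and RNA per cell cannot be told apart from a change in the mix of leukocytes.

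Genes of chromosome 12 shifted up together, 77 of 334 rising and 15 falling, with a median of 0.09 (camera, adjusted p = 0.00540; adjusted p = 0.343 with an estimated correlation). Genes of chromosome 8 (64 rose, 139 fell; adjusted p = 0.00268) and of X (27 rose, 70 fell; adjusted p = 0.00439) were lower, each with adjusted p = 0.343 with an estimated correlation. The injected lines may differ in copies of chromosome 12. The mean offset of its genes differed by 0.14 between the groups (two-sided exact permutation p = 0.0286, the smallest possible), with 0.10, 0.13 and 0.19 along its length. With the Ptprc covariate the adjusted p was 0.672 for chromosome 12, 0.672 for 8 and 2.89e-05 for X. That fit also called chromosomes 3 (lower, adjusted p = 0.0423), 13 (lower, 0.0345) and 15 (higher, 0.0380), which were not called without the covariate (0.202, 0.486 and 0.510). The calls of chromosomes 3, 8, 12, 13 and 15 thus depend on the covariate, while X was called lower in both fits at the preset correlation. For chromosome 12, copies in the lines cannot be told apart from a shift that goes with host cells.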
